A study of Mus musculus with 18 samples.

How the data were processed

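PolyA RNA was sequenced from C2C12 cells, a mouse skeletal muscle line that divides as mononuclear myoblasts and can be driven to differentiate into myotubes. Cells of each stage received a control siRNA or 1 of 2 siRNAs against Setd2, which encodes the histone methyltransferase that trimethylates lysine 36 of histone H3 in transcribed genes. Each of the 6 groups held 3 libraries labelled as biological replicates, 18 in all. Per the labels' protocols, RNA was taken directly after the cells had been stretched, and standard Illumina libraries were made. No unstretched group and no siRNA sequence was used here. Whether the libraries keep the strand of the RNA is not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart.

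The deposited tables, 1 per stage, list estimated counts and TPM (length-corrected transcript abundance as a share of its library, scaled within each library by the authors) for 115088 Ensembl transcripts in 9 libraries. Per the file headers, the columns are those of a transcript quantifier of the salmon type; its name, version and annotation are not given in the sources used here. The submitters' processing notes name the mm10 build and DESeq2 without stating their roles. The estimated counts deposited by the authors are not scaled between libraries and summed to between 43.5 and 66.6 megareads per library. Transcripts were matched by identifier to the GENCODE M21 annotation of mm10, which placed 114200 of them in 47311 genes; the 888 unmatched transcripts held 0.16% to 0.24% of the counts of a library and were left out. Counts were summed per gene and rounded to whole numbers. The tables hold no mitochondrially encoded gene, and nuclear pseudogenes of mitochondrial sequence (Gm29216, Gm28661, Gm10925 and Gm28437) took 1.11% to 1.71% of the counts, so mitochondrial reads may be counted there. Genes with near-identical copies, among them the Prl2c, Serpinb9 and histone genes, can share reads and their values are uncertain.

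Columns were assigned to samples by the library names in the labels. The column of the third myoblast library of siRNA 2 carries a name with SETD3 in its table, where the label of that sample has SETD2 and is otherwise the same. Setd2 was at 40.3 CPM (counts per megaread, scaled as below) in that library, against 45.1 and 46.1 in the other libraries of its group, and Setd3 was at 72.4 against 72.6 and 74.7, so it was kept, and each leading myoblast count is also given without it. The Setd2 level does not tell siRNA 2 from siRNA 1, whose myoblast mean was 40.15 CPM. Ribosomal RNA-like sequence took 4.1% of the counts of that library, against 1.46% and 1.9% in the others of its group. The name of the third myotube control holds NT_2, where the names of all other controls hold NT_1. Whether it received a different control siRNA is not given, so the myotube controls may not share 1 control siRNA. Library names begin with 1 of 2 prefixes in each stage (C14 and D2 in myoblasts, C13 and D1 in myotubes), whose meaning is not given. Every group holds both prefixes, in unequal numbers: C14 has 1 control, 2 siRNA 1 and 1 siRNA 2 libraries, with 2, 1 and 2 in D2, and C13 has 2, 1 and 1, with 1, 2 and 2 in D1. In myotubes a prefix difference would thus move both siRNAs the same way.

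Differential expression was tested with edgeR 4.0.16 in R 4.3.3: genes kept by filterByExpr (minimum count 10), TMM scaling, glmQLFit and glmQLFTest with robust estimates, and Benjamini-Hochberg adjustment, with a gene called at an adjusted p under 0.05. The 9 libraries of a stage were fitted together with 3 groups, leaving 6 residual degrees of freedom. Control myotubes against control myoblasts, and the difference of the depletion effect between stages, were tested in 1 fit of all 18 libraries with 6 groups and 12 residual degrees of freedom. The difference between stages is the mean of both siRNAs against control in myotubes minus the same mean in myoblasts. Standard errors of log2 fold changes were derived from the quasi-likelihood F statistic. CPM values are TMM-scaled, with SD over 3 libraries; those of a stage come from that stage's fit, and those that set the stages side by side come from the fit of all libraries. All adjusted p values below come from edgeR's quasi-likelihood test unless camera is named.

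Before the data were examined, 34 gene lists were fixed, covering muscle, cell cycle, DNA repair, stress, metabolism, matrix, signalling, chromatin and RNA processing genes and markers of other cell types. Lists with at least 3 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists of a comparison; a list was called for a stage when it passed in the same direction with each siRNA. Of the depletion lists called in this way, none passed with the correlation estimated from the data (0 of 6 in myoblasts and 0 of 10 in myotubes). The rule for named genes was also fixed in advance. For each stage it takes the 12 genes with the largest mean rise and the 12 with the largest mean fall among genes called the same way by each siRNA, with all 6 depleted libraries on one side of the 3 controls and mean log2 CPM above 1. It adds up to 4 called members of each list by adjusted p. For the other comparisons it takes the 6 largest changes in each direction with mean log2 CPM above 1, and for differentiation also up to 4 members of 4 lists. Predicted genes without a name were counted but not named, and fewer genes are named than the rule allows.

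The procedure was tested on simulated counts drawn from the means of the control libraries and the fitted dispersions, with 200 genes changed. With siRNA 1 in myoblasts, the test recovered 85% of the 1.5-fold and 96% of the 2-fold changes, and 7.65% of its calls were false; in myotubes these values were 86%, 96% and 4.21%. With siRNA 2 they were 78%, 91% and 7.14% in myoblasts and 86%, 98% and 8% in myotubes. They were 75%, 94% and 5.59% for the stages and 73%, 94% and 3.47% for the difference of effects. Both of these used the means of control myoblasts for all 18 libraries, so myotube means were not simulated there. In the data 20.03% to 33.5% of genes were called with an siRNA against control and 77.51% between the stages. Scaling and false calls were therefore not tested with as many genes changed. The simulated genes were uncorrelated, so the simulations do not test the preset correlation used for gene lists.

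Libraries of one group with the same prefix were closer to each other than those with different prefixes. The median chi-square of genes between 2 libraries was 0.69 to 1.39 in the 6 same-prefix pairs and 1.45 to 2.8 in the 12 other pairs, against 0.455 for sampling noise alone, over genes with at least 50 counts. The highest same-prefix value, 1.39, was that of myotube controls 1 and 3, whose names hold NT_1 and NT_2. No pair agreed within sampling noise, so none was taken as a library deposited more than once. These values do not show that same-prefix libraries came from separate cultures; if they did not, p values measure a spread that is partly technical. Adding the prefix to the model lowered the common coefficient of variation between replicates from 5.71% to 2.6% in myoblasts and from 6.19% to 4.16% in myotubes. Alternatives fixed in advance were RLE scaling, DESeq2 1.42.0, no expression filter, only the groups compared, a 2-fold minimum, the replicate number as a block, the prefix as a covariate, an estimated list correlation and leaving out each library in turn. After the data were seen, a sum of same-prefix libraries and limma on log2(TPM + 1) were added. Within a stage and for the difference of effects, sums were fitted with the prefix in the model. Summing alone was not tested there. Values under these alternatives stand beside a result only where they change it. Because both siRNAs share the controls, unchanged groups were simulated 50 times against the same controls for each stage, once without prefix differences and again with each gene's fitted prefix difference kept, the latter added after the data were seen. The 3 controls of a stage cannot be divided into parts of at least 2, so part of any agreement between the siRNAs may come from the shared controls.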

Results

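RNA abundance was measured by polyA RNA sequencing in C2C12 myoblasts and in myotubes differentiated from them, each transfected with a control siRNA, Setd2 siRNA 1 or Setd2 siRNA 2. There were 3 libraries per group and 18 in all. Total estimated counts ran from 52.3 to 57.2 megareads in control myoblasts, 53.2 to 63 megareads with siRNA 1 and 45.2 to 55.6 megareads with siRNA 2. In myotubes they ran from 43.5 to 66.6 megareads in controls, 51.2 to 56.4 megareads with siRNA 1 and 48.6 to 59.9 megareads with siRNA 2. Together, 2 genes made of ribosomal RNA sequence, CT010467.1 and AY036118, took 1.2% to 1.36% of the counts in control myoblasts, 3.56% to 3.91% with siRNA 1 and 1.46% to 4.1% with siRNA 2. In myotubes their share was 1.27% to 2.3% in controls, 1.5% to 2.88% with siRNA 1 and 2.26% to 2.99% with siRNA 2.

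Setd2, the targeted gene (ENSMUSG00000044791, chromosome 9, positions 110532597 to 110618633 of mm10), was lower in each of the 12 depleted libraries than in any control of its stage. In myoblasts it stood at 110.6 ± 10.4 CPM in controls (SD, n = 3), 40.15 ± 4.41 with siRNA 1 and 43.86 ± 3.09 with siRNA 2, falls of 63.7% and 60.3%. The log2 fold changes were -1.46 (SE 0.10, adjusted p = 1.69e-05) and -1.33 (SE 0.10, adjusted p = 1.14e-05). With same-prefix libraries summed and the prefix in the model, the call for siRNA 1 was lost (-1.464, adjusted p = 0.0541). That for siRNA 2 stayed (-1.295, adjusted p = 0.0466). In myotubes it stood at 103 ± 3.19 CPM in controls, 44.7 ± 11.6 with siRNA 1 and 35.53 ± 2.39 with siRNA 2, falls of 56.6% and 65.5%, with log2 fold changes of -1.20 (SE 0.17, adjusted p = 0.00299) and -1.54 (SE 0.17, adjusted p = 0.000581). Within the C13 prefix the 1 myotube library of siRNA 1 held 58.15 CPM, against 37.85 and 38.11 in the D1 libraries. The Setd2 levels of both siRNAs did not differ past the threshold in either stage (log2 difference of siRNA 2 from siRNA 1 0.13, SE 0.10, adjusted p = 0.406 in myoblasts; -0.33, SE 0.17, adjusted p = 0.247 in myotubes). Setd3, which encodes an actin histidine methyltransferase of the same domain family, rose with each siRNA in myoblasts (log2 fold changes 0.21 and 0.12, adjusted p = 0.00136 and 0.0217) and in myotubes (0.22 and 0.23, adjusted p = 0.00141 and 0.000596).

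**Figure D1:**
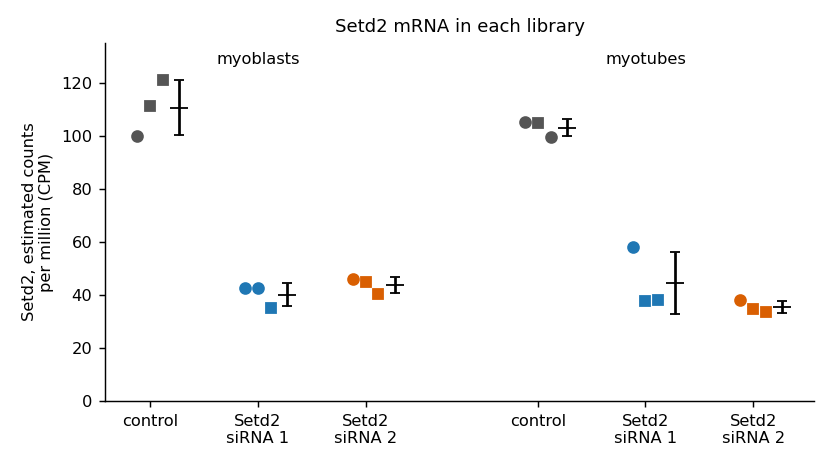
Setd2 level in each library (vertical axis, CPM) by stage and siRNA; points are single libraries, with circles for the prefixes C14 and C13 and squares for D2 and D1, and bars are mean and SD over 3 libraries. Every depleted library lies below every control of its stage, and 1 myotube library of siRNA 1 lies at 58.15 CPM.

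Control myotubes were compared with control myoblasts to show what differentiation changed in these cells. By list median, genes of the contractile apparatus rose most and genes of mitosis fell most. Of 48 sarcomere genes tested, 47 rose and 0 fell (47 and 0 adjusted over the list alone), with a median log2 fold change of 8.08, which stayed at 8.08 with the 3 genes absent from control myoblasts set to their bounds. Myl2, the slow myosin regulatory light chain, had 0 counts in the control myoblasts and 23.6 ± 2.18 CPM in myotubes, at least 1340-fold higher against a floor of 3 counts over the group. The largest single rises also include genes outside the contractile list with 0 counts in control myoblasts: Ppp1r3a, Gdf5 and Ighm, at least 945-, 881- and 865-fold higher. Mybpc2, fast myosin binding protein C, went from 1 count to 6605 counts over the 3 libraries, a ratio of 7080 with a 95% counting interval of 1270 to 280000. Myh2, a fast myosin heavy chain, rose from 0.105 ± 0.0146 to 109 ± 10.5 CPM. Cardiac troponin T Tnnt2 rose from 40.6 ± 1.86 to 1388 ± 91.9 CPM. The myogenic transcription factor Mef2c rose from 2.58 ± 0.297 to 379 ± 15.2 CPM (log2 fold change 7.20, SE 0.10, adjusted p = 2.77e-19).

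All 38 genes of the mitosis list fell on differentiation (38 adjusted over the list alone; median log2 fold change -2.65), as did 41 of 42 S-phase genes (41 adjusted over the list alone; -2.05) and 30 of 33 DNA repair genes (30 adjusted over the list alone; -1.76). Cyclin B1, Ccnb1, fell from 229.6 ± 2.87 to 25.85 ± 1.295 CPM. The replicative helicase subunit Mcm5 fell from 155.5 ± 2.01 to 24.5 ± 0.71 CPM (log2 fold change -2.67, SE 0.04, adjusted p = 1.92e-21). Among excitation-contraction coupling genes 26 of 28 rose and 1 fell (26 and 1 adjusted over the list alone), and all 44 cytosolic ribosomal protein genes fell (44 adjusted over the list alone; median -0.72). By camera the S-phase and DNA repair calls held with an estimated correlation (adjusted p = 0.0183 and 0.00469). The mitosis, sarcomere, coupling and ribosomal calls did not, with adjusted p = 0.139, 0.139, 0.103 and 0.33 with an estimated correlation. Fibroblast markers also rose, 9 of 11 against 1 that fell (9 and 1 adjusted over the list alone), with a median log2 fold change of 2.14. Camera gave adjusted p = 0.0194 for them, and 0.249 with an estimated correlation. Ngfr, the nerve growth factor receptor, fell from 23.8 ± 3.86 to 0.0811 ± 0.0143 CPM. Prl2c3, whose reads can be shared with its near-identical copies, stood at 456 ± 62.9 and 0.934 ± 0.385 CPM. In all, 6678 genes rose and 6445 fell among 16930 tested, 5539 of them by at least 2-fold. Stage, table and prefix change together, so no value within a prefix can be had for this comparison.

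Depletion in myoblasts was tested separately with each siRNA, since a change seen with both is less open to the sequence of either. Lhfp, a tetraspan membrane protein gene named as a fusion partner in a lipoma, rose from 20.5 ± 1.23 to 50.6 ± 1.16 and 53.2 ± 1.31 CPM (SD, n = 3; log2 fold changes 1.30 and 1.37, SE 0.05 each, adjusted p = 1.28e-08 and 5.33e-09; siRNA 1 first here and below). Peg10, an imprinted gene of retrotransposon origin, rose from 53.4 ± 4.16 to 117 ± 2.82 and 161 ± 9.75 CPM. Tmco1, which encodes a calcium channel of the endoplasmic reticulum, rose from 23 ± 0.727 to 51.4 ± 3.53 and 55.1 ± 0.271 CPM. Casp6, an executioner caspase, and Lats2, a kinase of the Hippo pathway, rose with log2 fold changes of 1.21 and 1.01 and of 0.83 and 1.23. Among the largest falls, Pappa, a metalloproteinase that cleaves insulin-like growth factor binding proteins, went from 9.16 ± 1.36 to 2.58 ± 0.181 and 3.35 ± 0.749 CPM (log2 fold changes -1.83 and -1.44, SE 0.16 and 0.15, adjusted p = 9.9e-06 and 2.06e-05).

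Single genes of interleukin signalling were among the falls in myoblasts, but interleukin signalling had no list of its own and was not tested. The NF-kB and cytokine list had 1 gene up and 1 down of 20 with each siRNA (1 and 1 adjusted over the list alone). With siRNA 2 taken alone that list rose, 9 up and 1 down (9 and 1 adjusted over the list alone; camera adjusted p = 0.0164, and 0.471 with an estimated correlation). Il1rl1, the receptor of interleukin 33, fell from 4.47 ± 1.01 to 1.48 ± 0.222 and 1.73 ± 0.215 CPM. Il33 itself fell from 51.6 ± 6.52 to 28.6 ± 2.28 and 34.5 ± 2.7 CPM. The interleukin 1 receptor antagonist Il1rn fell (log2 fold changes -1.23 and -1.28), as did the interleukin 6 receptor Il6ra (-0.81 and -1.26). The 3′ UTR of Il6ra holds the word GAGCGGA, whose carriers were on average lower with siRNA 2 (given among the observations). Wnt7b fell from 8.46 ± 0.862 to 4.59 ± 0.262 and 3.87 ± 0.571 CPM. Pdk4, a kinase that restrains pyruvate oxidation, fell from 33.7 ± 3.87 to 13.5 ± 1.24 and 21.5 ± 2.4 CPM. Of the interferon response list, 3 genes rose and 4 fell of 31 with each siRNA (3 and 4 adjusted over the list alone). The antiviral gene Ifit1 was among them (log2 fold changes -1.22 and -0.57).

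Of the 32 lists tested in myoblasts, 6 were called with each siRNA. Extracellular matrix genes rose, 17 of 48 against 2 that fell (21 and 2 adjusted over the list alone; median log2 fold changes 0.19 and 0.34). Fibrillin 1, Fbn1, rose from 187 ± 3.17 to 268 ± 5.23 and 336 ± 12 CPM, and thrombospondin 2, Thbs2, from 150.7 ± 5.48 to 213 ± 5.92 and 199.8 ± 8.04 CPM. Camera's call for this list was lost with adjusted p = 0.387 and 0.179 with an estimated correlation. Fibroblast markers were not called (camera adjusted p = 0.21 and 0.0768), with medians of 0.32 and 0.28 and 2 of 7 rising with each siRNA (3 adjusted over the list alone). Tubulins and microtubule regulators rose, 11 of 26 with none falling (13 and 0 adjusted over the list alone; adjusted p = 0.254 and 0.41 with an estimated correlation). They were led by Map1a (0.47 and 0.63), Vash2, an enzyme that removes the terminal tyrosine of tubulin (0.61 and 0.50), and Tubb2b (0.50 and 0.49). Genes of the integrated stress and unfolded protein response rose, 6 of 34 with none falling (10 and 0 adjusted over the list alone; adjusted p = 0.254 and 0.187 with an estimated correlation). The chaperone Canx rose from 481 ± 23.9 to 718 ± 14 and 739.5 ± 9.39 CPM. Mitosis genes rose, 12 of 38 against 2 that fell (14 and 2 adjusted over the list alone; medians 0.09 and 0.12; adjusted p = 0.672 and 0.557 with an estimated correlation). Plk1 stood at 0.30 and 0.37 and Foxm1 at 0.28 and 0.36. Excitation-contraction coupling genes rose, 8 of 25 against 2 that fell (8 and 2 adjusted over the list alone; adjusted p = 0.732 and 0.684 with an estimated correlation). The acetylcholine receptor subunit Chrna1 stood at 0.28 and 0.34 and junctophilin 1, Jph1, at -0.69 and -0.48. Splicing factor genes fell, 5 of 37 against 1 that rose (6 and 1 adjusted over the list alone; adjusted p = 0.387 and 0.471 with an estimated correlation). Srsf4 stood at -0.14 and -0.32. On the TPM scale the counts were 2 up and 1 down for coupling genes, 5 up and 2 down for mitosis genes and 1 up and 11 down for splicing genes, and the medians of the 6 lists kept their signs. With siRNA 1 alone more mitosis genes fell than rose on that scale, 6 against 5 (median 0.018).

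Other lists passed camera with 1 siRNA in myoblasts. Myogenic regulators rose with siRNA 2 (13 of 26, 0 falling; 14 and 0 adjusted over the list alone; camera adjusted p = 0.000493, and adjusted p = 0.323 with an estimated correlation). With both siRNAs 4 of the 26 rose (4 adjusted over the list alone), among them M-cadherin, Cdh15, at 0.40 and 0.51. Sarcomere genes rose with siRNA 2 (9 of 38, 0 falling; 9 and 0 adjusted over the list alone; adjusted p = 0.713 with an estimated correlation), and desmin, Des, rose with each (0.34 and 0.46). YAP/TAZ and SRF targets rose with siRNA 2 (12 of 35, 2 falling; 12 and 2 adjusted over the list alone; adjusted p = 0.684 with an estimated correlation), and calponin 2, Cnn2, rose with each (0.83 and 0.64). NF-kB, cholesterol synthesis and TGF-beta lists also rose with siRNA 2, with 9, 15 and 13 members rising and 1, 2 and 2 falling (9, 20 and 13 rising and 1, 4 and 2 falling adjusted over the list alone) and adjusted p = 0.471, 0.684 and 0.526 with an estimated correlation. Interferon genes and osteoblast and chondrocyte markers fell with siRNA 1, 10 of 31 against 3 that rose and 2 of 7 against 0 (10 against 3 and 2 against 0 adjusted over the list alone), with adjusted p = 0.544 and 0.254 with an estimated correlation.

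With siRNA 1, 1807 genes rose and 1315 fell of 15586 tested in myoblasts, 103 of them by at least 2-fold, and with siRNA 2, 2658 rose and 2564 fell, 172 of them by at least 2-fold. Each siRNA moved 1861 genes the same way, 1198 up and 663 down, 30 of them by at least 2-fold with each, and 162 genes were called in opposite directions. Lists as long drawn independently would share 308.2 rises and 216.3 falls. Groups simulated without change against the same controls shared 0.06 calls on average and 2 at most (0 on average and at most with the prefix differences kept). Since no gene was changed in the simulated groups, few shared calls were given by construction. How many the shared controls add among genes changed by 1 siRNA was not simulated. The covariance of the fold changes was 0.0674 against 0.0228 simulated (0.0189 with the prefix differences kept). With the prefix in the model, 5029, 7215 and 3086 genes were called with siRNA 1, siRNA 2 and each. With the prefix in the model and same-prefix libraries summed as well, the counts were 4461, 6609 and 2638. On the TPM scale the median gene moved by -0.05 with siRNA 1 and -0.03 with siRNA 2. The share of calls that were rises went from 57.9% to 27.7% with siRNA 1, from 50.9% to 36.9% with siRNA 2 and from 64.4% to 35.3% with each. With RLE scaling these shares were 55%, 51% and 62.4%. TMM and RLE both leave the median gene near no change (0.005 and -0.002 with siRNA 1), so their likeness is no independent check. TPM was not scaled between libraries, and the ribosomal RNA genes CT010467.1 and AY036118 took a larger share of it in depleted myoblasts. Their share was 1.49% to 1.72% in controls, 4.51% to 4.93% with siRNA 1 and 1.84% to 5.2% with siRNA 2. A larger share lowers the TPM of all other genes, so it adds to the fall of the median gene, by an amount not computed. With limma on TPM, unit and test also change together. The balance of rises and falls is therefore not settled. Left out in turn, replicates 1 and 2 of siRNA 1 and replicates 2 and 3 of the controls gave 2016, 2075, 2013 and 1959 genes for siRNA 1. Without the siRNA 2 library named SETD3 the counts were 2797, 4288 and 1589 for siRNA 1, siRNA 2 and each.

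**Figure D2:**
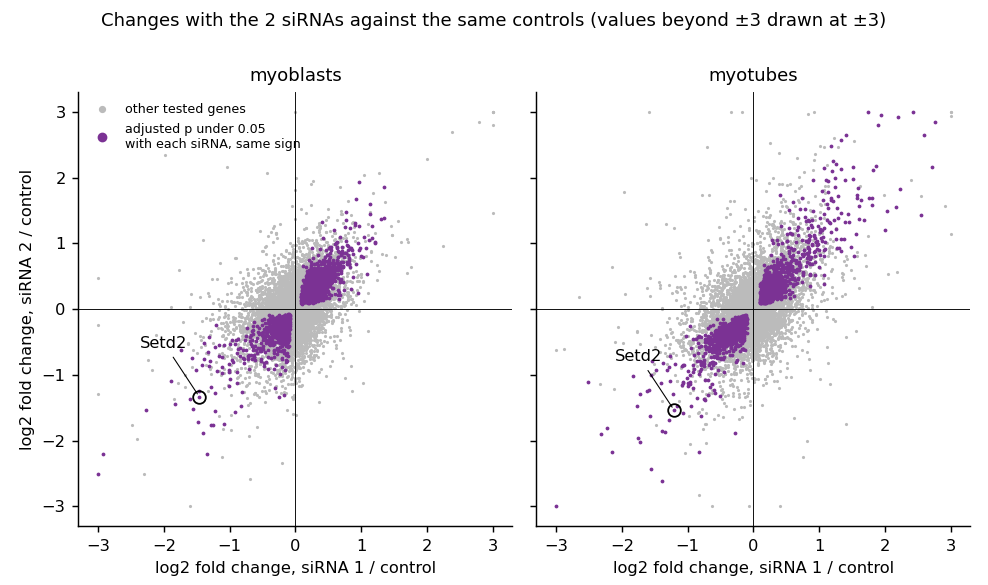
Log2 fold change against control with siRNA 2 (vertical axis) and with siRNA 1 (horizontal axis) for every tested gene in myoblasts and myotubes; purple points are called with each siRNA in the same direction and Setd2 is circled. Purple points number 1861 in myoblasts and 2160 in myotubes, and both axes share the controls, which alone give a correlation of 0.492 and 0.497 in simulated unchanged groups (0.455 and 0.555 with the prefix differences kept) against 0.55 and 0.609 observed.

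In myotubes, the same comparison was made with each siRNA, and the lists of mitosis, S phase and DNA repair were called as falling. Of 38 mitosis genes, 37 fell with each siRNA and none rose (37 and 0 adjusted over the list alone), with median log2 fold changes of -0.52 and -0.42. Topoisomerase 2a, Top2a, fell from 112 ± 4.67 to 70.3 ± 2.57 and 75 ± 1.59 CPM (log2 fold changes -0.67 and -0.58, SE 0.04 each, adjusted p = 4.13e-06 and 1.66e-06). Mki67, the Ki-67 antigen, fell from 151 ± 5.13 to 105 ± 2.17 and 113 ± 5.16 CPM. Camera's call for the list was lost with adjusted p = 0.188 and 0.381 with an estimated correlation. Within the C13 prefix the medians were -0.53 and -0.36, and within D1 -0.51 and -0.46. Control myotubes already held these genes far below control myoblasts, as given above. S-phase genes fell, 23 of 42 with none rising (24 and 0 adjusted over the list alone; medians -0.28 and -0.30; adjusted p = 0.188 and 0.381 with an estimated correlation). They include Uhrf1 (-0.52 and -0.56) and Mcm4 (-0.37 and -0.45). DNA repair genes fell, 12 of 33 with none rising (15 and 0 adjusted over the list alone; medians -0.26 and -0.26; adjusted p = 0.112 and 0.226 with an estimated correlation). Bard1 stood at -0.62 and -0.81 and Brca1 at -0.47 with each. With siRNA 2 taken alone, 1 S-phase gene and 1 DNA repair gene rose (2 and 1 adjusted over the list alone).

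**Figure D3:**
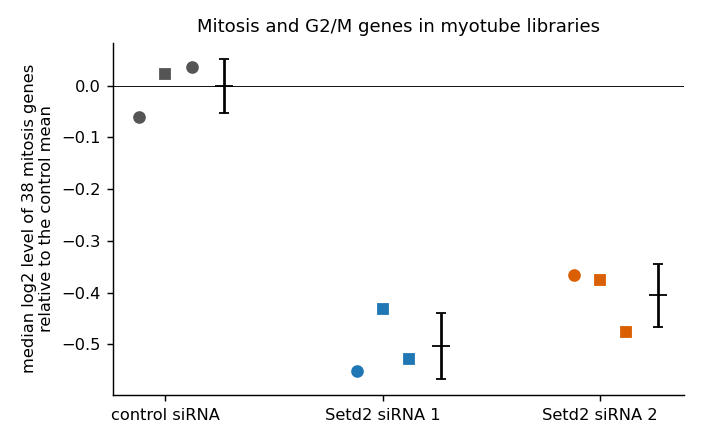
Median log2 level of the 38 mitosis and G2/M genes in each myotube library relative to the control mean (vertical axis) by siRNA; points are single libraries, circles for prefix C13 and squares for D1, and bars are mean and SD over 3 libraries. Controls lie between -0.06 and 0.04 and depleted libraries between -0.55 and -0.37.

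The lists of oxidative phosphorylation, excitation-contraction coupling, sarcomere and ribosomal protein genes were called as rising in depleted myotubes, with most members of each list not called with each siRNA. Of 45 nuclear-encoded oxidative phosphorylation genes, 19 rose with each siRNA and none fell (25 and 0 adjusted over the list alone; medians 0.10 and 0.29; adjusted p = 0.338 and 0.381 with an estimated correlation). The rise was larger with siRNA 2, where 40 rose (41 adjusted over the list alone). Compared directly, 35 were higher with siRNA 2 than with siRNA 1 and 0 lower (37 and 0 adjusted over the list alone). Camera gave adjusted p = 2.08e-17 for this difference, and 0.565 with an estimated correlation. The muscle form of a cytochrome oxidase subunit, Cox7a1, rose from 3.3 ± 0.525 to 5.33 ± 0.151 and 9.42 ± 0.833 CPM. Uqcrc2, a core subunit of complex III, rose from 110 ± 3.39 to 136 ± 0.729 and 156 ± 1.89 CPM. Excitation-contraction coupling genes rose, 9 of 28 with none falling (10 and 0 adjusted over the list alone; adjusted p = 0.338 and 0.481 with an estimated correlation). Both calcium pumps rose, Atp2a1 (0.32 and 0.67) and Atp2a2 (0.32 and 0.47). Sarcomere genes rose, 11 of 48 against 2 that fell (13 and 3 adjusted over the list alone; medians 0.15 and 0.17; adjusted p = 0.338 and 0.481 with an estimated correlation). With siRNA 2 taken alone, 4 coupling and 6 sarcomere genes fell (4 and 6 adjusted over the list alone). Fast troponin I, Tnni2, rose by 0.33 and 0.47. Myh4, the fastest myosin heavy chain, fell from 513 ± 38.2 to 262.5 ± 26.6 and 256.4 ± 17.6 CPM (SE of the log2 fold changes 0.08 each, adjusted p = 9.57e-05 and 2.78e-05). Acetylcholinesterase, Ache, rose from 7.36 ± 0.417 to 13.8 ± 1.42 and 28.6 ± 2.69 CPM. Colq, its collagen anchor at the neuromuscular junction, rose from 7.49 ± 1.54 to 16.3 ± 0.471 and 25.4 ± 4.45 CPM. Cytosolic ribosomal protein genes rose, 4 of 44 with none falling (4 and 0 adjusted over the list alone; adjusted p = 0.62 and 0.575 with an estimated correlation). On the TPM scale the counts were 7 up and 1 down for oxidative phosphorylation, 7 up and 3 down for sarcomere and 1 up for ribosomal genes, and the medians of these lists kept their signs.

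Lists of stress response genes, YAP/TAZ and SRF targets and splicing factors fell in depleted myotubes. Genes of the integrated stress and unfolded protein response fell, 10 of 34 with none rising (10 and 0 adjusted over the list alone; medians -0.23 and -0.12; adjusted p = 0.188 and 0.389 with an estimated correlation). The chaperone Hspa5 fell from 644 ± 25.2 to 546 ± 20.8 and 493 ± 20.5 CPM. YAP/TAZ and SRF targets fell, 8 of 35 against 3 that rose (12 and 4 adjusted over the list alone; adjusted p = 0.205 and 0.381 with an estimated correlation). Filamin A, Flna, stood at -0.37 and -0.39 and Egr3 at -0.78 and -0.80, while Lats2 rose (0.27 and 0.39). Splicing factor genes fell, 5 of 37 with none rising (5 and 0 adjusted over the list alone; adjusted p = 0.488 and 0.575 with an estimated correlation), and 14 fell on the TPM scale. The TGF-beta and BMP list was not called with siRNA 2 (4 up and 8 down of 31; 4 and 11 adjusted over the list alone; camera adjusted p = 0.262), and 5 of its genes fell with each siRNA (6 adjusted over the list alone). Inhba, an activin subunit, fell from 18.3 ± 1.39 to 9.2 ± 0.821 and 8.46 ± 0.518 CPM. Id3, an inhibitor of myogenic transcription factors, fell from 15.1 ± 1.03 to 7.26 ± 0.439 and 8.35 ± 1.14 CPM. Pappa fell here too, from 16 ± 1.45 to 4.52 ± 0.621 and 7.97 ± 1.49 CPM. The collagen Col8a2 fell from 5.78 ± 1.16 to 1.01 ± 0.25 and 2.67 ± 0.0447 CPM (log2 fold changes -2.51 and -1.11, SE 0.19 and 0.17, adjusted p = 1.65e-05 and 0.000392). Among the largest rises were Scara5, a ferritin receptor (log2 fold changes 1.33 and 2.57), Epas1, a hypoxia-inducible transcription factor (1.08 and 2.14), and Gpr37 (2.54 and 1.44).

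Markers of other cell types and the lists called with 1 siRNA moved less evenly in myotubes. Fibroblast markers rose, 5 of 11 with siRNA 1 and 3 with siRNA 2, none falling (5 and 3 adjusted over the list alone), and epithelial markers rose, 2 of 4 and 1 of 4 (3 and 3 adjusted over the list alone). Camera called both with siRNA 1, lost at adjusted p = 0.338 for each with an estimated correlation. All 4 tested endothelial markers rose with siRNA 2 (4 adjusted over the list alone; median log2 fold change 0.95; adjusted p = 0.381 with an estimated correlation) and 0 of 4 were called with siRNA 1. With siRNA 1, 15 of 50 matrix, 7 of 31 TGF-beta and 8 of 31 Wnt and Notch genes fell (17, 7 and 9 adjusted over the list alone), called by camera and lost at adjusted p = 0.531, 0.188 and 0.338 with an estimated correlation, while 4, 2 and 2 rose (4, 2 and 2 adjusted over the list alone). With siRNA 2 camera called none of them: matrix genes stood at 6 up and 7 down (6 and 6 adjusted over the list alone) and Wnt and Notch genes at 10 up and 4 down (11 and 4 adjusted over the list alone; median log2 fold change 0.09). Autophagy and lysosome genes rose with siRNA 1, 12 of 39 against 1 that fell (12 and 1 adjusted over the list alone; their median changes sign on the TPM scale; adjusted p = 0.376 with an estimated correlation). With siRNA 2, 11 of 35 glycolysis genes rose against 4 that fell, and 10 of 26 tubulin genes fell against 2 that rose (11 and 4, and 10 and 2, adjusted over the list alone), lost at adjusted p = 0.389 and 0.481 with an estimated correlation.

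In myotubes 1766 genes rose and 1540 fell with siRNA 1 of 16097 tested, 216 of them by at least 2-fold, and 2545 rose and 2640 fell with siRNA 2, 392 of them by at least 2-fold. Each siRNA moved 2160 genes the same way, 1150 up and 1010 down, 104 of them by at least 2-fold with each, and 82 were called in opposite directions. Independent lists as long would share 279.2 rises and 252.6 falls, and simulated unchanged groups shared 0.04 calls on average and 1 at most (0.02 and 1 with the prefix differences kept). Few shared calls were given by construction here too. The covariance of the fold changes was 0.0858 against 0.0242 simulated (0.0262 with the prefix differences kept). With the prefix in the model, 4405, 6070 and 2859 genes were called with siRNA 1, siRNA 2 and each. With same-prefix libraries summed the counts were lower than without either change, at 2487, 4280 and 1638. On the TPM scale the median gene moved by -0.05 and -0.08. The 2 ribosomal RNA genes held 1.69% to 3.03% of TPM in controls. They held 2.01% to 3.83% with siRNA 1 and 2.95% to 3.87% with siRNA 2, which overlaps the controls, unlike in myoblasts. The share of calls that were rises went from 53.4% to 30.6% with siRNA 1, from 49.1% to 25.2% with siRNA 2 and from 53.2% to 25.5% with each. Replicates 2 and 3 of siRNA 1 decided part of the siRNA 1 count, which was 2156 and 2042 without them. Without control replicate 2, 1439 genes were called with each siRNA.

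Depleted myoblasts and myotubes shared few changes. Of 14825 genes tested in both stages, 204 rose and 93 fell with each siRNA in both, where independent lists would share 84.9 and 42.7. Another 110 rose in myoblasts and fell in myotubes (78.7 for independent lists), and 20 fell in myoblasts and rose in myotubes (46 for independent lists).

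**Figure D4:**
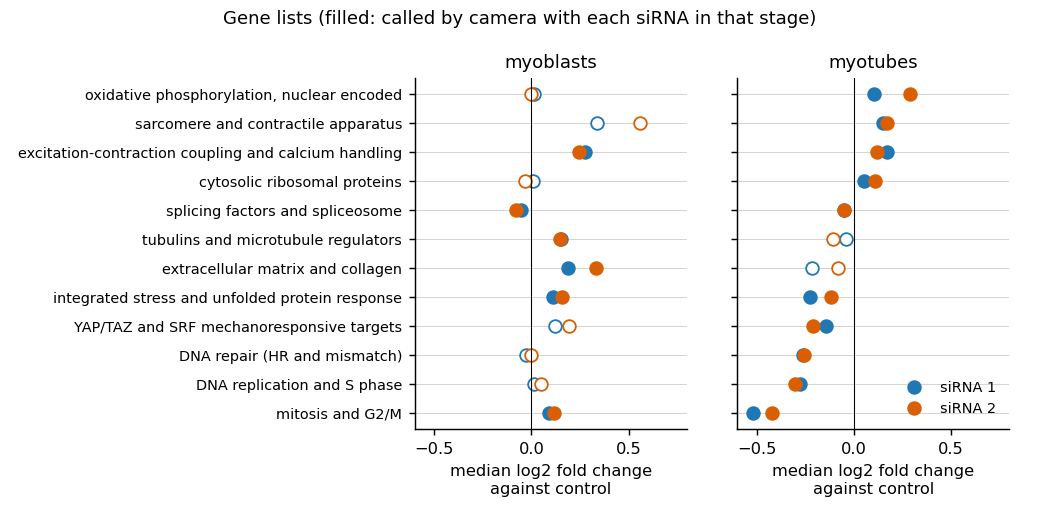
Median log2 fold change against control (horizontal axis) of the gene lists called with each siRNA in at least 1 stage, in myoblasts and myotubes; blue is siRNA 1, orange is siRNA 2, and filled points mark stages in which camera called the list with each siRNA. Mitosis genes have medians of 0.09 and 0.12 in myoblasts and -0.52 and -0.42 in myotubes.

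Compared directly, the siRNAs differed from each other in both stages. In myoblasts Ccnd2, cyclin D2, stood at 87.4 ± 4.06 CPM in controls, 51.7 ± 1.56 with siRNA 1 and 104 ± 2.28 with siRNA 2 (log2 difference of siRNA 2 from siRNA 1 1.01, SE 0.04, adjusted p = 1.29e-08). Integrin beta 3, Itgb3, followed the same order at 51.5 ± 3.33, 37.8 ± 1.26 and 73.5 ± 1.73 CPM. The phosphatase gene Dusp9 stood at 14.8 ± 2.07, 26.7 ± 5.89 and 6.24 ± 1.36 CPM (log2 difference -2.10). Zdhhc4, a palmitoyltransferase, was lower with siRNA 2 in myoblasts (log2 difference -1.40) and in myotubes (-1.30), and Cpt2, the mitochondrial carnitine transferase, was lower in myoblasts (-1.31). Ankrd13a was lower with siRNA 2 as well (-1.31), and the 3′ UTRs of Cpt2 and Ankrd13a hold the word GAGCGGA. In myotubes the mTOR inhibitor Deptor fell with each siRNA (log2 fold changes against control -0.28 and -1.88, adjusted p = 0.00745 and 3.37e-08) and differed between the siRNAs by -1.60. Sema3c stood at 96.7 ± 4.07, 129 ± 4.33 and 50.5 ± 2.13 CPM (log2 difference -1.35, SE 0.04, adjusted p = 4.85e-09).

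Between the siRNAs 1880 genes were higher and 2223 lower with siRNA 2 in myoblasts (93 of them by at least 2-fold), and 1249 higher and 1506 lower in myotubes (190 of them by at least 2-fold). With the prefix in the model 6263 and 4030 genes were called in myoblasts and myotubes, and with same-prefix libraries summed as well 5741 and 1979. Without the siRNA 2 library named SETD3, 3092 were called in myoblasts. On the TPM scale the share of calls higher with siRNA 2 went from 45.8% to 54.3% in myoblasts, which reverses the majority there. In myotubes it went from 45.3% to 33.9%. Without replicate 2 or 3 of siRNA 1 or replicate 2 of siRNA 2, 1814, 1762 and 1817 genes were called in myotubes. With siRNA 2 taken as the reference in myoblasts, 2656 genes differed the same way in control and siRNA 1 libraries, more than the 1861 that set both siRNAs apart from control; with siRNA 1 as the reference 945 did. In myotubes the counts were 2160 against control, 1736 against siRNA 2 and 649 against siRNA 1.

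The effect of depletion differed between stages for 3962 of the genes tested in both stages together, 1796 with a higher and 2166 with a lower log2 fold change in myotubes. Mitosis genes moved furthest apart as a list, 37 of 38 lower in myotubes and none higher (37 and 0 adjusted over the list alone; median log2 difference -0.55; adjusted p = 0.0673 with an estimated correlation). S-phase genes (31 of 42 lower; 32 adjusted over the list alone), DNA repair genes (18 of 33 lower and 1 higher; 19 and 1 adjusted over the list alone) and stress response genes (17 of 34 lower and 1 higher; 25 and 1 adjusted over the list alone) also differed, and their calls held with an estimated correlation (adjusted p = 0.0363 for each). Oxidative phosphorylation genes differed the other way, 31 of 45 higher and 2 lower (37 and 2 adjusted over the list alone; median 0.21; adjusted p = 0.206 with an estimated correlation). This difference averages both siRNAs, and the myotube rise of these genes was larger with siRNA 2. Wnt7b fell in myoblasts and stood at 0.767 ± 0.11, 1.11 ± 0.0443 and 1.39 ± 0.138 CPM in control, siRNA 1 and siRNA 2 myotubes (log2 difference of the effect 1.68, SE 0.17, adjusted p = 7.38e-07). Col8a2 stood at 2.42 ± 0.234, 2.45 ± 0.211 and 2.73 ± 0.329 CPM in myoblasts and fell in myotubes (log2 difference -1.91, SE 0.19, adjusted p = 8.15e-07). With the prefix in the model 5426 genes were called, and with same-prefix libraries summed as well 4099. Without the siRNA 2 myoblast library named SETD3 the count was 3729.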

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

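The explanation by microRNAs of the miR-1 family was chosen after the mitosis result had been seen; the tests of ribosomal RNA, prefix and differentiation were written down earlier. All results in this part differ between the stages by a test of the difference itself. Depletion changed 3962 genes differently in myotubes and myoblasts. Of 60 divisions of the same 18 libraries, drawn at random but for the real one, 1 called as many genes, the real one, and the highest other called 761. That other division kept the 3 myotube controls as controls. Mixing groups puts real differences into the spread, so lower counts in the other divisions were partly given by construction.

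As median log2 differences of the effect (myotube minus myoblast), the lists that passed camera were mitosis and G2/M at -0.545 (adjusted p = 0.0673 with an estimated correlation), S phase at -0.27 (adjusted p = 0.0363 with an estimated correlation), stress and unfolded protein response at -0.33 (adjusted p = 0.0363 with an estimated correlation) and DNA repair at -0.249 (adjusted p = 0.0363 with an estimated correlation). Extracellular matrix stood at -0.357 (adjusted p = 0.309 with an estimated correlation), tubulins at -0.231 (adjusted p = 0.0805 with an estimated correlation), YAP/TAZ and SRF targets at -0.21 (adjusted p = 0.366 with an estimated correlation), myogenic regulators at -0.202 (adjusted p = 0.206 with an estimated correlation) and TGF-beta and BMP genes at -0.096 (adjusted p = 0.366 with an estimated correlation). Higher in myotubes were oxidative phosphorylation at 0.215 (adjusted p = 0.206 with an estimated correlation), cytosolic ribosomal proteins at 0.1 (adjusted p = 0.633 with an estimated correlation) and epithelial markers at 0.367 (adjusted p = 0.309 with an estimated correlation).

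The single genes with the largest differences upward were Tmem252 (2.12, with under 0.05 CPM in myoblasts), Mlip (1.92, adjusted p = 0.0493), Wnt7b (1.68), Foxq1 (1.66), Grb14 (1.6) and Ctsc (1.56). Those downward were Col8a2 (-1.91), Tmprss11f (-1.81), Palm3 (-1.54), Tas1r1 (-1.49), Ndst4 (-1.48) and Synpo2l (-1.47).

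The fall of mitosis genes in myotubes was weighed against technical and biological explanations. Carry-over of ribosomal RNA does not account for it: of the depleted libraries, 3 lie inside the control range of the ribosomal RNA-like share, and the highest of them is still below the lowest control by a log2 difference of -0.305, against 0.098 between the controls. A difference of 1 library-name prefix does not account for it either, since the highest of the 4 medians within a prefix and siRNA was -0.356. Across genes outside the mitosis, S-phase and sarcomere lists, the change on depletion followed the change on differentiation with a slope of 0.0388 (interval 0.0339 to 0.0438, r = 0.267). The interval comes from resampling genes and does not measure the spread between libraries. The shared myotube controls push this slope below 0, so a small shift toward further differentiation could contribute. DNA repair genes, which fell on differentiation and on depletion, stayed in and add to the slope. In myoblasts, where mitosis genes rose, the slope was 0.0428 (interval 0.0367 to 0.0502); the shared controls push it upward there, so the slopes of the stages cannot be compared. For the muscle microRNAs of the miR-1 family the test was undecided, with their site at rank 1 among the 7-base words under siRNA 1 and at rank 212 under siRNA 2. Carriers of this site were also the lowest in control myotubes against control myoblasts (rank 1, -0.25 log2). The site therefore cannot tell this explanation from a shift toward further differentiation.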

How the results depend on the processing

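Summing same-prefix libraries and limma on log2(TPM + 1) were chosen after the data were seen. Of 9160 alternative values for 524 named values of 260 genes, 8765 kept direction and side of the threshold, 394 lost the call and 1 reversed: Mtor with siRNA 2 in myoblasts, -0.01 (adjusted p = 0.907) with limma on TPM; the cause was not tested. Of the lists called with each siRNA, none passed with an estimated correlation (0 in myoblasts, 0 in myotubes). With the prefix in the model, myoblast calls rose to 5029 for siRNA 1, 6263 between the siRNAs and 3086 for each, where replicate spread was lower. A 2-fold minimum, stricter by construction, left 103, 172, 93 and 30 genes in myoblasts (siRNA 1, siRNA 2, between them, each), 216, 392, 190 and 104 in myotubes and 5539 between the stages. Setd2 with siRNA 1 in myoblasts was at -1.464 (adjusted p = 0.0541) with same-prefix libraries summed and the prefix in the model, which leaves fewer samples.

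Leaving out 1 library gave, in the same order, 1959 to 3431, 4215 to 5529, 3092 to 4314 and 1253 to 1936 genes in myoblasts with 5 to 7 lists, and 2042 to 4068, 3920 to 5382, 1762 to 3196 and 1439 to 2491 in myotubes with 9 to 11 lists. Between the stages it gave 12699 to 13291 genes, and 3279 to 4138 for the difference of effects. Setd2 ranged from -1.538 to -1.372 and -1.409 to -1.266 in myoblasts and from -1.43 to -1.092 and -1.59 to -1.486 in myotubes.

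With the replicate number as a block, 4334, 6222, 5322 and 2581 genes were called in myoblasts and 3738, 5570, 3177 and 2441 in myotubes. Between groups, deviations of libraries from their group means correlated above 0.1 in 7 of 9 same-number pairs and in 13 of 13 same-prefix pairs in each stage. Of the 14 pairs with different prefixes 0 did, so the same-number pairs above 0.1 all share a prefix. The numbers are taken as labels only. No value with the prefix in the model exists between the stages. At 43.5 to 66.6 megareads per library, same-prefix libraries had a median chi-square of 0.69 to 1.39 against 0.455 for sampling noise in genes with at least 50 counts, so counting noise adds to the spread beyond genes of a few counts.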

Other observations

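The tests of a stronger Setd2 depletion by siRNA 2 and of seed matches of siRNA 1 in myoblasts were chosen after the difference between the siRNAs had been seen; the other tests of seed matches and that of gene length were written down earlier.

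Genes that carry a certain short word in their 3′ UTRs were on average lower with siRNA 2 than with siRNA 1. Carriers of GAGCGGA were lower by -0.25 log2 in siRNA 2 than in siRNA 1 myoblasts (202 of 10618 genes searched) and by -0.138 in myotubes (213 of 10983), rank 1 of all 7-base words in each stage; the test took the leading word in myoblasts and asked for its rank in myotubes, which was 1. The word occurs in the Setd2 transcript. How many of all 7-base words occur there was not counted, so such an occurrence alone carries little weight, here and below. With siRNA 2 against control, 54.5% of carriers fell in myoblasts against 21.3% of other genes (47.9% against 21.0% in myotubes). Seed pairing of siRNA 2 could thus lower genes such as Cpt2, Ankrd13a and Il6ra directly. In myoblasts and myotubes, carriers of this word make up 4.7% and 6.1% of the genes called lower with siRNA 2 than with siRNA 1. They also make up 38 of the 1861 and 45 of the 2160 genes moved by each siRNA, counts that pool rises and falls. Among genes lowered by each siRNA, where seed pairing would act, carriers were 28 of 663 in myoblasts and 29 of 1010 in myotubes. The overlapping words AGCGGAA (-0.19 log2 in myoblasts), AGAGCGG (-0.139) and AGCGGAC (-0.151) came next in myoblasts, at ranks 2 to 4; genes with these words and without GAGCGGA are not in these shares.

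The same search for siRNA 1 gave AAAGATC in myoblasts, which ranked 1734 in myotubes. That test followed 1 word, and TCACCCC, singled out after its ranks were seen, which also occurs in the Setd2 transcript, ranked 10 in myoblasts (-0.029 log2) and 1 in myotubes (-0.032), so seed matches of siRNA 1 stay undecided in both stages. The lowest words in myoblasts, AAAGATC, AGATCGA and AAGATCG, overlap and occur in the Setd2 transcript. AGATCGA was rank 1 under siRNA 1 against control, with carriers lower by -0.109 log2, and rank 2 against siRNA 2 (-0.094), but rank 3842 against siRNA 2 in myotubes (-0.016). Stronger depletion by siRNA 2 was not seen at the mRNA level in myoblasts, where Setd2 was 0.127 log2 higher with siRNA 2 (SE 0.0983). That difference is near its SE and the protein was not measured, so stronger depletion is not excluded there. It stays undecided in myotubes at -0.332 (SE 0.1688).

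Setd2 marks transcribed gene bodies, so longer genes were tested for more frequent changes. Genes moved by each siRNA in myoblasts had a median span of 29249 bp against 24009 bp in genes matched for expression, a ratio of 1.218 (permutation p = 0.0001, the smallest possible). In myotubes the ratio was 1.076 (permutation p = 0.0062), too small to decide. In myoblasts exonic length differed as well, by a ratio of 1.076 (permutation p = 0.0001), and in myotubes its ratio was 1.013 (permutation p = 0.4382). For myotube genes that rose and that fell, the span ratios were 0.848 and 1.321, the exonic length ratios 0.872 and 1.191, and the median GC contents 51.71% and 48.67% against 49.89% and 50.05% in matched genes, so span, exonic length and GC content move together there and are not separated.

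The libraries were also divided in other ways. Of the 10 possible divisions of each 3 against 3, 1 called as many genes, the real one, which is too few to set it apart at 5%. The highest other called 1 gene for siRNA 1 in myoblasts and for siRNA 2 in myotubes and 0 in the other comparisons. Each of these others mixes both groups on both sides, which puts any real difference into the spread, so few calls were given by construction. For genes moved by each siRNA, 1 of 100 divisions (the real one and others drawn at random) called as many in either stage, and the highest others called 1669 in myoblasts and 951 in myotubes, each with the siRNA 2 libraries as the reference.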
